A study of Mus musculus with 4 samples.

How the data were processed

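RNA was measured in neural progenitor cells, the dividing cells of the developing brain from which neurons and glia arise. Per the labels' protocols, they were dissected from the forebrain of C57BL/6 mouse embryos at embryonic day 14 and grown in a proliferation medium with 2% B27 supplement and the mitogens EGF and FGF-2, each at 20 ng/ml. A lentivirus carried a short hairpin RNA against Rybp, a protein that binds the catalytic core of Polycomb repressive complex 1, into the cells of one group, and the other group is labelled as the control, with its vector not given in the sources used here. Each group has 2 libraries with replicate numbers 1 and 2. The labels do not say that replicates came from separate cultures, animals or infections, so p-values measure only the spread between these libraries, which may be technical. Total RNA was extracted with TRIzol and made into libraries by standard Illumina protocols, per the labels' protocols. Strand information is not given in the sources used here.

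The deposited table gives raw read counts per gene and library, whole numbers that the authors did not normalize, beside FPKM values (counts scaled by gene length and library size) that the authors computed from them. For each gene the ratio of count to FPKM changed between libraries by 1 factor per library, with a largest relative difference between genes of 6.0e-08, so the FPKM values carry no correction beyond these. The build is mm10 per the submitters' processing notes. The aligner, the counting program and their settings are not given in the sources used here. The table holds 13881 genes, each with a total of at least 40 counts over the 4 libraries, so genes below that level were not analysed here. Of the genes, 12187 are protein-coding, 823 are processed pseudogenes and 579 are long non-coding RNAs. Gene symbols, starts and ends are those of the table. A spreadsheet had turned 21 symbols into dates, and these were restored from the Ensembl identifiers. Chromosomes and strands came from GENCODE release M21 on the same build, in which 13870 identifiers were found and 13749 had the same start and end as in the table. Where a symbol stood in more than 1 row (2 symbols), the row with more counts stood for it in gene lists.

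Total counts were 17598873 in control 1, 15938646 in control 2, 14355308 in shRybp 1 and 16400480 in shRybp 2. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 5.30 over 13424 genes between the control libraries and 4.49 over 13224 genes between the shRybp libraries, so they were kept as separate samples.

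Groups were compared with edgeR 4.0.16 (TMM scaling, quasi-likelihood fit and two-sided test) in R 4.3.3, on the counts of the 12062 genes with a mean FPKM of at least 1 over the 4 libraries, with Benjamini-Hochberg adjustment over all genes tested and a threshold of adjusted p 0.05. Before the data were examined the table was taken to hold FPKM alone and limma on log2(FPKM + 1) was planned, with edgeR to take its place if counts were found; the limma fit is kept as an alternative. Standard errors were taken as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic, and intervals are 95% intervals from the t distribution with the fit's degrees of freedom. In the text a gene rose or fell in shRybp only if it passed this test. FPKM values are given as mean ± SD over the 2 libraries of a group. The fit was tested on simulated data drawn with the mean levels of the control libraries, the real library sizes and the fitted dispersions. For the comparison of shRybp with control over 12062 genes, 57 of 67 genes changed by 1.5-fold were found, 65 of 67 changed by 2-fold and 66 of 66 changed by 3-fold. In that simulation 22 unchanged genes passed the threshold, and 3 genes passed when no gene was changed. The unchanged genes were a larger share of the simulated calls than a threshold of adjusted p 0.05 aims at. Far fewer genes were changed in the simulation than were called in the data, so these rates may not carry over.

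The 30 gene lists were written, also at that stage, from general knowledge of Notch signalling, neural progenitors and their progeny, other cell types of the forebrain, the cell cycle, Polycomb complexes, lineage genes under Polycomb control, signalling, stress and metabolism. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on the edgeR fit with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists tested. Camera asks whether the genes of a list moved against all other genes, and fry asks whether they moved, on balance, in 1 direction. With an estimated correlation camera takes its p-values from the few degrees of freedom left by 4 libraries, so a list can hardly pass. Counts of members that rose or fell are given over all genes tested and with p-values adjusted over the list alone.

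The genes named in the text follow a rule set at the same stage. Rybp comes first, then the 12 largest rises and 12 largest falls in log2(FPKM + 1) among genes past the threshold whose shRybp values both lay on the same side of both control values, then 18 fixed genes of the Notch pathway, Polycomb complexes and neural cells, and up to 4 members of each list with the smallest p. Numbered and cloned gene models, pseudogenes and near-identical ribosomal and histone copies were counted but not named. A gene that makes up a count of 5 or fewer, or that is singled out in the closing observations, was named after its values were seen.

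Alternatives set at the same stage were no filter on low values, a minimum mean FPKM of 5, a fit with the replicate number as a block, each library left out in turn, a minimum fold of 1.5, and, for limma, a pseudocount of 0.1, a median shift, quantile normalization, no variance trend and robust moderation. Limma on log2(FPKM + 1), first planned as the main test, became an alternative once counts were found. Alternatives added after seeing the data were DESeq2 1.42.0, DESeq2 size factors in edgeR, library totals without TMM, and counts thinned to the smallest library. Tables were handled with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.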

Results

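Transcripts of cultured mouse forebrain neural progenitor cells were counted in 2 control libraries and 2 libraries of cells infected with a lentivirus expressing a short hairpin RNA against Rybp (shRybp). Total counts per library were between 14355308 and 17598873. Libraries of 1 group were closer to each other than to the other group, with a Pearson correlation of log2 library-scaled counts across the tested genes of 0.994 between the controls and 0.994 between the shRybp libraries, against 0.981 to 0.983 between groups. The comparison asks which genes change when Rybp is depleted in dividing progenitors, with the genes of Notch signalling and of Polycomb repressive complex 1 (PRC1), in which Rybp is a subunit, as its main subject.

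The targeted gene was lower in both shRybp libraries. Rybp (ENSMUSG00000072872, mm10 chromosome 6, 100228565 to 100287485, minus strand) had an FPKM of 4.43 in control 1, 3.95 in control 2, 3.01 in shRybp 1 and 2.66 in shRybp 2, from 370, 299, 205 and 207 counts. The level in shRybp was 65.8% of control, a log2 fold change of -0.60 (SE 0.12, 95% interval -0.86 to -0.35) with an edgeR adjusted p of 0.0017. About 66% of the transcript therefore remained in these cultures. Yaf2, the paralogue of Rybp in the same complexes, had 28.0 ± 2.17 FPKM in control and 28.7 ± 1.06 in shRybp and did not pass the test (log2 fold change -0.00, 95% interval -0.19 to 0.18, edgeR adjusted p = 0.97).

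Of 12062 genes tested, 1970 rose and 2013 fell in shRybp, together 33.0% of the genes. Most changes were small, with a median absolute log2 fold change of 0.40 among the genes that passed. Only 340 genes rose and 587 fell by 1.5-fold or more, and 70 rose and 146 fell by 2-fold or more. The values of the groups did not overlap for 8137 genes, 67.5% of those tested, where chance gives 33.3% for 2 libraries against 2. Without shRybp replicate 2 the number of genes that rose was 1296. The balance of rises and falls depends on scaling, with 2361 and 1718 genes under library totals without TMM and 1982 and 1442 in limma on log2(FPKM + 1).

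Spp1, which encodes the secreted matrix protein osteopontin, rose from 4.61 ± 0.09 to 20.8 ± 1.80 FPKM, a log2 fold change of 2.14 (SE 0.11, edgeR adjusted p = 8.8e-08), among the largest rises. Itga4, an integrin subunit, rose from 1.87 ± 0.08 to 8.49 ± 0.78 FPKM (log2 fold change 2.15, SE 0.09, edgeR adjusted p = 1.2e-08). Tmem173, which encodes the DNA-sensing adaptor STING, rose by 1.77 on the log2 scale, and the p53-inducible gene Trp53i11 by 1.59. The others were Lgals3bp (log2 fold change 1.72), Kdelr3 (1.47), Cd93 (1.37), the metalloprotease gene Adam19 (1.25), the calcium-dependent membrane-binding protein gene Anxa6 (1.24) and Igfbp4 (1.19), which encodes a binding protein of insulin-like growth factors. Dynlt1c (1.503) and Srp54b (1.34) also belong here, but both have near-identical neighbours with which reads can be shared, so their values are uncertain. Of these copies, Dynlt1f (0.32) and the pseudogene Dynlt1-ps1 (0.22) also rose, and Dynlt1a, Dynlt1b and Srp54c did not pass the test.

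The largest fall was that of Apoe, the main lipid carrier made by astrocytes (mm10 chromosome 7, 19696109 to 19699188), from 232 ± 1.69 to 38.9 ± 3.92 FPKM, 6.11-fold lower (log2 fold change -2.61, SE 0.07, edgeR adjusted p = 7.8e-10). Gpr17, a receptor of oligodendrocyte precursors, followed with 18.3 ± 1.61 and 3.32 ± 0.50 FPKM (log2 fold change -2.51, SE 0.11, edgeR adjusted p = 2.0e-08). Gpr17 lies within Lims2 on the opposite strand, and reads of these genes cannot be told apart without strand information. The Notch effector Hes5 (-1.79) and the astrocyte filament gene Gfap (-1.83) were among the same 12 genes, as were Pla2g7 (-1.95), Ttyh1 (-1.90), Ndrg2 (-1.86), Mmd2 (-1.75), the cysteine dioxygenase gene Cdo1 (-1.72), Plekhb1 (-1.61) and the metallothionein gene Mt2 (-1.49). The mitochondrial transfer RNA gene mt-Tw (-2.26, SE 0.53) completes them, from a very short locus in which FPKM is imprecise, and it lost the call without control replicate 1 (edgeR adjusted p = 0.068) and with robust limma (adjusted p = 0.12).

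**Figure D1:**
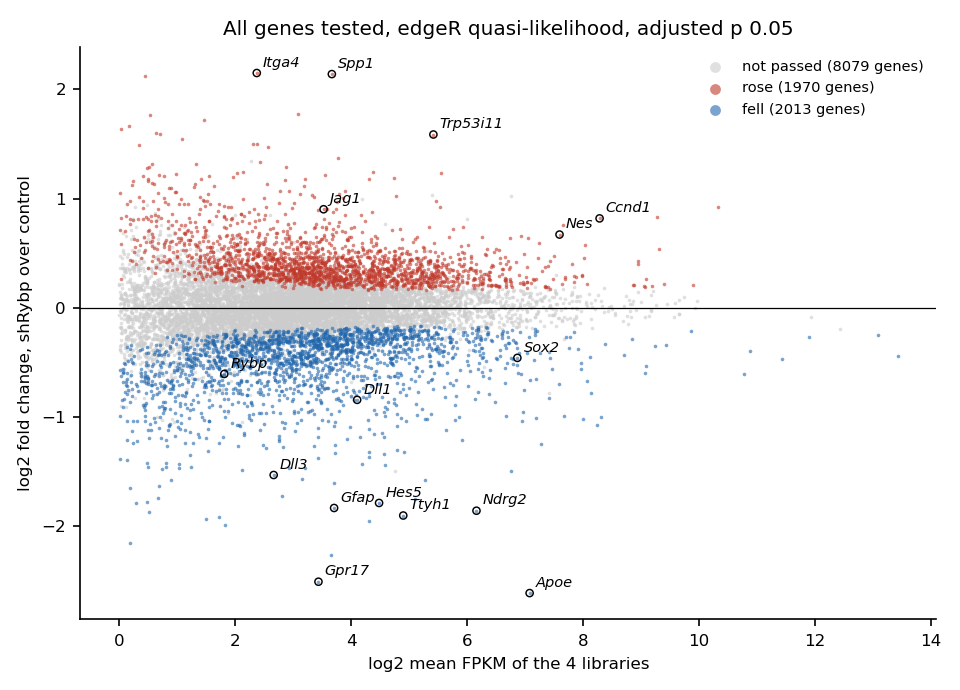
Log2 fold change of shRybp over control against the log2 mean FPKM of the 4 libraries for each of 12062 genes. Red points are the 1970 genes that rose and blue points the 2013 that fell at an edgeR adjusted p under 0.05, grey points are the 8079 others, and circled genes are named; Apoe (-2.61) and Gpr17 (-2.51) lie lowest and Itga4 (2.15) and Spp1 (2.14) near the top.

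Notch target genes were lower in shRybp as a group, with exceptions. Of 10 tested, 7 fell and 2 rose, the same numbers as adjusted over the list alone, and the median log2 fold change was -0.37 (camera adjusted p = 0.0019; adjusted p = 0.42 with an estimated correlation). Hes5, the Notch-induced repressor that holds progenitors undifferentiated (mm10 chromosome 4, 154960923 to 154962371), fell from 34.5 ± 0.77 to 10.2 ± 1.67 FPKM, 3.45-fold (log2 fold change -1.79, SE 0.11, edgeR adjusted p = 2.6e-07). Nrarp, a feedback inhibitor of Notch, fell from 26.2 ± 1.08 to 13.1 ± 0.46 FPKM (log2 fold change -1.03, SE 0.08, edgeR adjusted p = 2.5e-06), and the repressor gene Hey1 fell from 14.2 ± 0.41 to 8.04 ± 0.28 FPKM (log2 fold change -0.86, SE 0.09, edgeR adjusted p = 1.6e-05). Ccnd1, which encodes cyclin D1 and has inputs other than Notch, rose from 223 ± 1.46 to 403 ± 6.45 FPKM (log2 fold change 0.82, SE 0.07, edgeR adjusted p = 2.3e-06). Myc, also a target of mitogen signalling, was the other gene that rose (0.18). Hes1, the other main effector in progenitors, had 9.94 ± 0.44 FPKM in control and 11.2 ± 0.36 in shRybp and did not pass the test (log2 fold change 0.14, 95% interval -0.06 to 0.35, edgeR adjusted p = 0.27). Of the 10 genes, 4 (Fabp7, Hes1, Hes5 and Sox9) are also in the list of radial glia markers, and markers of astrocytes fell in the same libraries. The call of the list ended under quantile normalization of log2 FPKM (limma camera adjusted p = 0.053).

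Ligands of the pathway moved in opposite directions while the receptor Notch1 did not pass the test. Dll1, a ligand made by cells that begin to differentiate, fell from 21.9 ± 0.20 to 12.5 ± 1.39 FPKM (log2 fold change -0.84, SE 0.08, edgeR adjusted p = 1.1e-05), and the divergent ligand gene Dll3 fell from 9.36 ± 0.77 to 3.31 ± 0.30 FPKM (log2 fold change -1.53, SE 0.11, edgeR adjusted p = 1.5e-06). Jag1, another ligand, rose from 7.90 ± 0.01 to 15.1 ± 0.79 FPKM (log2 fold change 0.90, SE 0.08, edgeR adjusted p = 3.1e-06). Neurl1a, a ubiquitin ligase that acts on Notch ligands, rose from 0.80 ± 0.10 to 2.46 ± 0.02 FPKM (log2 fold change 1.59, SE 0.14, edgeR adjusted p = 4.0e-06), and overlaps an unnamed gene model on its own strand. Notch1 had 23.7 ± 1.96 FPKM in control and 23.1 ± 1.49 in shRybp (log2 fold change -0.07, 95% interval -0.22 to 0.08, edgeR adjusted p = 0.49). Notch2 fell by 0.26 on the log2 scale (edgeR adjusted p = 0.033) and Rbpj, the DNA-binding partner of the receptors, rose by 0.20 (edgeR adjusted p = 0.043), but each lost the call under 11 alternatives, leaving out control replicate 2 among them. Of 36 pathway components tested, 7 rose and 12 fell, the same numbers as adjusted over the list alone. The list as a whole did not move in 1 direction beyond the other genes (median log2 fold change -0.09, camera adjusted p = 0.32).

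**Figure D2:**
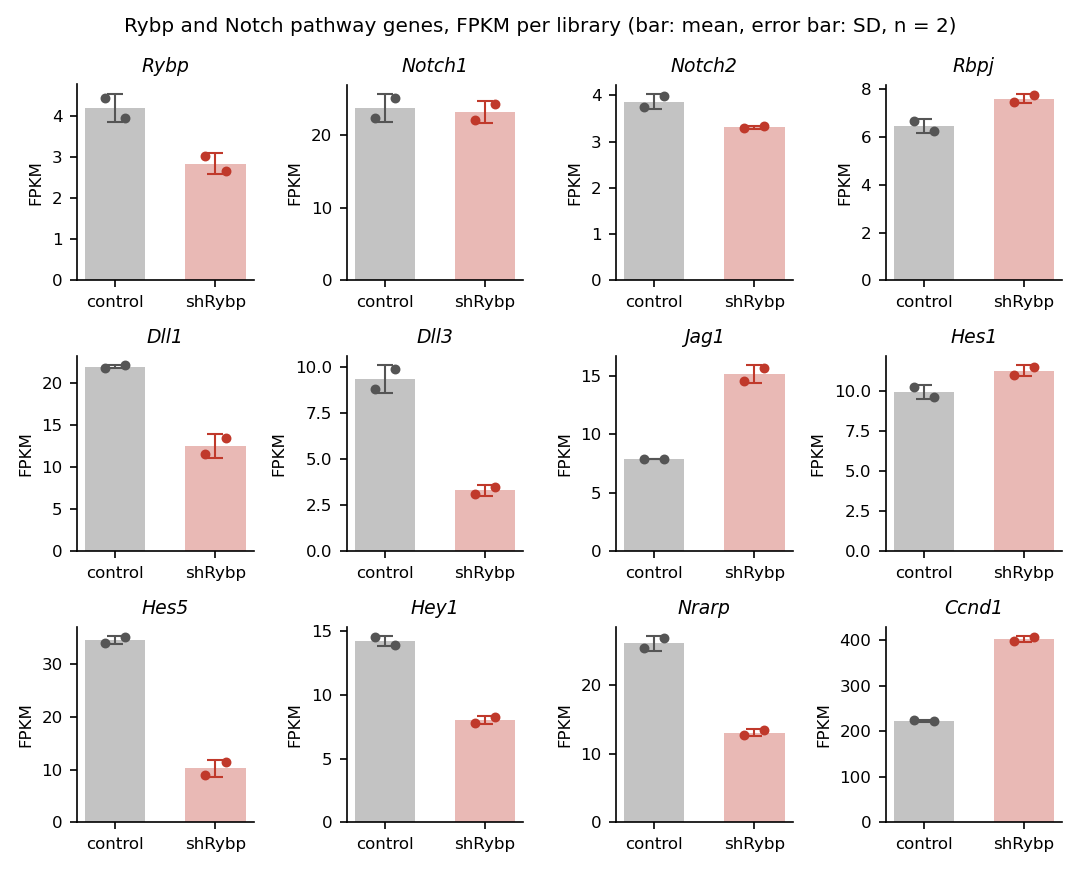
FPKM of Rybp and 11 genes of the Notch pathway in the 4 libraries, on linear axes from 0. Points are libraries, bars are group means and error bars are SD (n = 2); Hes5 fell from 34.5 to 10.2 FPKM and Jag1 rose from 7.90 to 15.1 FPKM, while the points of Notch1 overlap between groups.

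Subunits of Polycomb complexes changed little. Of 35 tested, 9 rose and 1 fell (8 and 1 adjusted over the list alone), the median log2 fold change was 0.06 and the list was not past the threshold (camera adjusted p = 0.21). The catalytic subunits of PRC1 did not pass the test. Ring1 had 4.51 ± 0.18 FPKM in control and 5.09 ± 0.16 in shRybp (log2 fold change 0.14, 95% interval -0.10 to 0.38, edgeR adjusted p = 0.37), and Rnf2 had 21.2 ± 1.75 and 22.7 ± 0.17 FPKM (log2 fold change 0.06, 95% interval -0.10 to 0.23, edgeR adjusted p = 0.54). Members that rose included Bcor (0.38) and L3mbtl2 (0.37), which belong to variant PRC1 complexes. Suz12 (0.32), a core subunit of the other repressive complex, and the histone-binding subunit gene Rbbp7 (0.39) rose too. The member that fell was Pcgf3 (-0.30). Genes that Polycomb complexes silence in neural cells were mostly too low to test. None of the 39 Hox genes listed was tested, and of 37 regulators of non-neural lineages 2 were tested, of which Prrx1 rose (log2 fold change 0.45) and Eya1 fell (-0.72). Of 22 germline genes 2 were tested and did not pass, Zcwpw1 (log2 fold change -0.20, edgeR adjusted p = 0.099) and Stag3 (0.19, edgeR adjusted p = 0.39).

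Astrocyte markers fell almost throughout. Of 19 tested, 16 fell and 1 rose (17 and 1 adjusted over the list alone), with a median log2 fold change of -0.69 (camera adjusted p = 2.1e-33; adjusted p = 0.16 with an estimated correlation). Beside Apoe, the filament gene Gfap fell from 20.3 ± 0.72 to 5.82 ± 1.03 FPKM (log2 fold change -1.83, SE 0.10, edgeR adjusted p = 2.0e-07), the glutamate transporter gene Slc1a2 fell by 1.11 on the log2 scale and the glycolytic enzyme gene Aldoc fell by 1.01. Cd44, an adhesion receptor that neural progenitors can also express, was the member that rose (0.32).

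Oligodendrocyte lineage markers fell in part. Of 15 tested, 7 fell and 0 rose, the same numbers as adjusted over the list alone, and the median log2 fold change was -0.40 (camera adjusted p = 3.8e-10; adjusted p = 0.42 with an estimated correlation). The precursor genes Pdgfra (-1.26) and Sox10 (-1.99) fell with Gpr17, as did Cnp (-0.80), which overlaps Dnajc7 on the opposite strand.

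Radial glia and stem cell markers were split. Of 23 tested, 10 fell and 4 rose (11 and 4 adjusted over the list alone), with a median log2 fold change of -0.19 (camera adjusted p = 0.00093; adjusted p = 0.42 with an estimated correlation). Sox2, a transcription factor of neural stem cells, fell from 134 ± 5.56 to 99.95 ± 2.39 FPKM (log2 fold change -0.46, SE 0.06, edgeR adjusted p = 0.00014), and lies within the non-coding gene Sox2ot. The glutamate transporter gene Slc1a3 (-0.67) and the growth factor receptor gene Fgfr3 (-0.77), which is also in the astrocyte list, fell too. Nes, which encodes the progenitor filament nestin, rose from 147 ± 2.30 to 240.1 ± 5.13 FPKM (log2 fold change 0.67, SE 0.06, edgeR adjusted p = 1.0e-05), and the other members that rose were Vim (0.27), Tnc (0.21) and Gli3 (0.38). Pax6 did not pass the test, at 3.45 ± 0.03 FPKM in control and 3.48 ± 0.15 in shRybp (log2 fold change -0.02, edgeR adjusted p = 0.85).

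Neuronal genes were at low levels in these proliferating cultures and also split. Of 15 neuron markers tested, 8 fell and 3 rose (11 and 3 adjusted over the list alone), with a median log2 fold change of -0.35 (camera adjusted p = 0.0079; adjusted p = 0.42 with an estimated correlation). Dcx, a microtubule-associated protein of young neurons, fell from 1.71 ± 0.17 to 0.76 ± 0.15 FPKM (log2 fold change -1.22, SE 0.14, edgeR adjusted p = 4.4e-05), and Mapt (-1.05) and Scg3 (-0.67) fell as well. Gap43, a growth cone protein, rose by 0.76 on the log2 scale, with Syt1 (0.72) and Kif5c (0.72). Tubb3 had 7.12 ± 0.70 FPKM in control and 8.36 ± 0.34 in shRybp and did not pass the test (log2 fold change 0.20, edgeR adjusted p = 0.22). Of 12 proneural and intermediate progenitor genes, 5 fell and 3 rose (7 and 3 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.012; adjusted p = 0.42 with an estimated correlation). Those that fell were Dll1, Dll3, Sox4 (-0.77), Btg2 (-0.40) and Tcf4 (-0.19), and those that rose were Insm1 (1.01), Gadd45g (0.62) and Sox11 (0.29). The neuron call ended with no filter on low values (camera adjusted p = 0.076), and both calls ended under quantile normalization (limma camera adjusted p = 0.053). Of the GABAergic lineage genes 3 were tested and did not pass, among them Gsx1 (log2 fold change -0.21) and Gsx2 (0.17).

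Genes of the cell division cycle rose together. Of 35 S phase genes 31 rose and 0 fell (33 and 0 adjusted over the list alone), with a median log2 fold change of 0.47 (camera adjusted p = 4.8e-18; adjusted p = 0.42 with an estimated correlation). Among them were the replicative helicase genes Mcm5 (0.72) and Mcm2 (0.65), the maintenance methylation factor gene Uhrf1 (0.74) and the ribonucleotide reductase gene Rrm2 (0.66). Of 38 genes of G2 and M phase 26 rose and 0 fell (29 and 0 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 1.1e-10; adjusted p = 0.42 with an estimated correlation), including the mitotic kinase gene Plk1 (0.65), Tubb4b (0.59), Gtse1 (0.55) and Anln (0.48). Mki67 had 134 ± 2.04 FPKM in control and 156 ± 11.4 in shRybp (log2 fold change 0.19, SE 0.07, edgeR adjusted p = 0.061). Of 24 p53 targets and arrest genes 7 rose and 3 fell, the same as adjusted over the list alone, and the list was not past the threshold (camera adjusted p = 0.081). Plk2 (0.60), Pidd1 (0.71) and Aen (0.40) rose, and the members that fell were the cell cycle inhibitor genes Cdkn1c (-1.035) and Cdkn2b (-0.59) and Trp53inp1 (-0.18), listed after their values were seen.

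**Figure D3:**
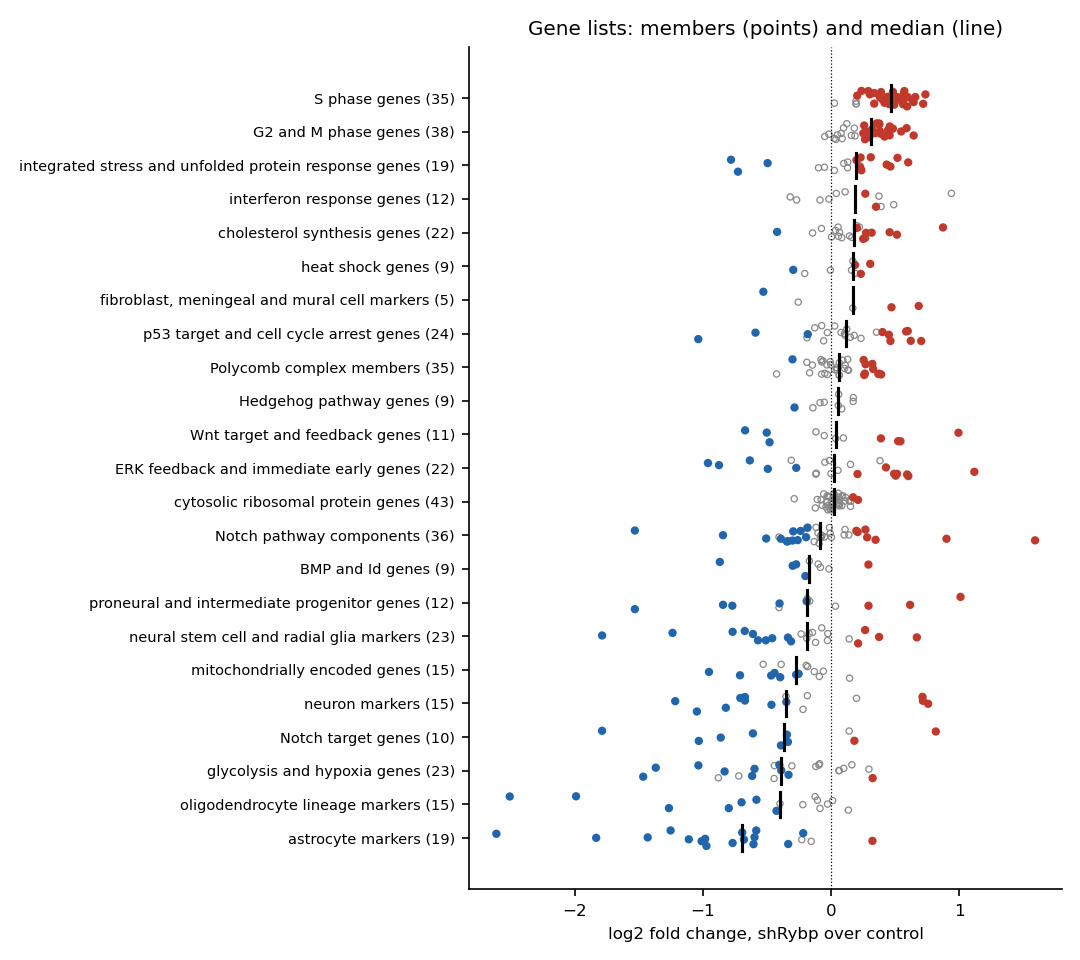
Log2 fold change of shRybp over control for the members of each of 23 gene lists, with the number tested in brackets. Filled red points rose and filled blue points fell at an edgeR adjusted p under 0.05, open points did not pass and black lines are medians; the S phase list has the highest median (0.47) and the astrocyte list the lowest (-0.69).

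Of 22 ERK feedback and immediate early genes tested, 8 rose and 5 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.21), with rises of the phosphatase genes Dusp4 (1.12) and Dusp6 (0.51) and of Spry4 (0.52) and falls of the immediate early genes Egr1 (-0.63), Egr2 (-0.96), Egr3 (-0.87) and Fos (-0.49) and of Spred1 (-0.27). Of 11 Wnt target genes 4 rose and 3 fell, the same as adjusted over the list alone (camera adjusted p = 0.47), with rises of Axin2 (0.54), Fzd1 (0.53), Tcf7 (1.00) and Lgr5 (0.39) and falls of Wnt7b (-0.50), Fzd7 (-0.67) and Tcf7l1 (-0.48). Of 9 BMP and Id genes 1 rose and 4 fell, the same as adjusted over the list alone (camera adjusted p = 0.081), and these were Bmp7 (0.29), the receptor genes Bmpr1b (-0.87) and Bmpr2 (-0.30), Id2 (-0.27) and Smad5 (-0.20). Of 9 Hedgehog genes Ptch1 fell (-0.29) and the other 8 did not pass, in both adjustments (camera adjusted p = 1.00; median log2 fold change 0.06). The mean of that list was -0.0013, fry gave its direction as down (fry adjusted p = 0.45) and camera as up.

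Of 22 cholesterol synthesis genes 8 rose and 1 fell (10 and 1 adjusted over the list alone), with a median log2 fold change of 0.18 (camera adjusted p = 0.0062; adjusted p = 0.61 with an estimated correlation). The sterol isomerase gene Ebp rose (0.52) and Msmo1 fell (-0.42), and the call of the list ended without control replicate 2 (camera adjusted p = 0.077). Of 15 mitochondrially encoded genes 7 fell and 0 rose, the same as adjusted over the list alone, with a median of -0.27 (camera adjusted p = 0.0025; adjusted p = 0.61 with an estimated correlation), among them mt-Co3 (-0.71), mt-Nd5 (-0.47), mt-Co1 (-0.44) and mt-Nd4 (-0.40). Their transcripts took 5.22% and 4.73% of counts in the controls and 4.09% and 3.92% in the shRybp libraries. Under quantile normalization of log2 FPKM the median of this list was only -0.06. Of 23 glycolysis and hypoxia genes 9 fell and 1 rose, the same as adjusted over the list alone, with a median of -0.39 (camera adjusted p = 0.028; adjusted p = 0.75 with an estimated correlation). Pdk1 (-1.47), Bnip3 (-1.37), Vegfa (-1.03) and P4ha1 (-0.61) fell and Pfkp rose (0.33). These genes also differed between replicates of a group, Pdk1 having 7.90 and 14.3 FPKM in the controls and 2.82 and 5.35 in the shRybp libraries, and the list lost its call without control replicate 2 (camera adjusted p = 0.55) and without shRybp replicate 1 (camera adjusted p = 0.13).

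Other lists were not past the threshold. Of 19 genes of the integrated stress and unfolded protein responses 9 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.099), Asns (0.60) and Shmt2 (0.44) among the first and Dnajb9 (-0.78), Ddit4 (-0.73) and Ddit3 (-0.49) making up the second. Of 9 heat shock genes 3 rose, Hsph1 (0.31), Dnajb1 (0.23) and Hspa8 (0.19), and Hspa4l fell (-0.29) (5 and 2 adjusted over the list alone; camera adjusted p = 0.35). Of 12 interferon response genes, a list of interest because lentivirus was used, Ifitm3 (0.35) and Stat2 (0.27) rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.37). Of 43 ribosomal protein genes 2 rose, Rps2 (0.21) and Rpl27 (0.17), and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.43). Of 5 markers of fibroblasts, meninges and mural cells Acta2 (0.69) and Foxc1 (0.47) rose and Col6a1 fell (-0.53) (2 and 2 adjusted over the list alone; camera adjusted p = 0.69). Of 18 microglial markers 2 were tested and did not pass, among them Cd68 (log2 fold change 0.66, edgeR adjusted p = 0.10), and no endothelial or red blood cell marker was high enough to test.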

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

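Limma on log2(FPKM + 1), first planned as the main test, was made an alternative once counts were found. DESeq2, DESeq2 size factors, library totals without TMM and thinned counts were chosen after seeing the data. Rybp stayed lower in shRybp and past the threshold in each of the 16 alternatives in which it was tested, with log2 fold changes of -0.70 to -0.44 and adjusted p of 3.5e-05 to 0.021. Leaving out 1 library in turn gave 1296 to 1640 genes higher and 1481 to 1760 lower, the lowest of each without shRybp replicate 2, with fewer samples and the lone library assumed to vary like the other group. A minimum fold of 1.5 left 340 higher and 587 lower by construction. DESeq2 called 1371 and 1447 genes, of which 1368 and 1444 were shared with edgeR. No alternative called a gene in the opposite direction. With the replicate number as a block the counts were 2676 and 2652. Same-numbered libraries deviated together with a correlation of 0.10 over genes. With 2 pairs this does not settle whether the numbers mark pairs, and the labels do not say so. No list was past the threshold with an estimated correlation. The camera adjusted p was then 0.16 for astrocyte markers. It was 0.42 for the Notch target, radial glia, proneural, neuron, oligodendrocyte, S phase and G2 and M phase lists. The estimated correlation was 0.0125 for the astrocyte list and -0.042 for the proneural list, against the preset 0.01. The correlation itself therefore does not account for the loss of these calls. With an estimated correlation camera takes p-values from the few degrees of freedom left by 4 libraries in 2 groups. With the preset correlation it takes them from the number of genes. The unadjusted camera p of the astrocyte list was 9.2e-35 with the preset and 0.0068 with the estimated correlation. In these 2 lists the loss therefore reflects the few libraries. In the other lists named here the estimated correlation was 0.071 (neuron) to 0.33 (S phase), and the share of each difference was not tested. Fry kept the astrocyte list (adjusted p = 0.0091) and gave 0.05385 for the Notch target, proneural, neuron, oligodendrocyte, S phase and G2 and M phase lists and 0.05394 for radial glia, against 0.13 for the cholesterol synthesis and mitochondrially encoded lists and 0.47 for glycolysis and hypoxia; the cause was not tested. Quantile normalization gave an adjusted p of 0.053 for the Notch target, proneural and neuron lists. The proneural list had an adjusted p of 0.063 after a median shift and 0.074 without a variance trend, and the neuron list had 0.076 with no filter; the cause was not tested. Camera has no robust setting, and DESeq2 gives no list test, so these were not run for lists. List medians kept their sign under each of 6 other scalings. Of 107 named genes past the threshold beside Rybp, 84 stayed past it in each alternative that tested them. With 2 simulated libraries per group at these depths, 85.1% of 1.5-fold changes were found.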

Other observations

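Of the tests below, that of GC content and gene length was set before its value was seen; the tests of gene families, depth, glial share, replicate numbers and myelin transcripts were chosen after seeing the data. Among 116 families of at least 10 genes that share the letters of their symbols, 8 had a camera adjusted p under 0.05, namely Nup, Mcm, Adamts, Sox, Gpr, Aldh, Eif and Snx. No family passed with an estimated correlation, where Gpr and Snx had a camera adjusted p of 0.86, Aldh 0.88 and Eif 0.95. Of the Mcm genes, most of which are also in the S phase list, 8 of 10 were higher and 0 lower, with a median log2 fold change of 0.45 (camera adjusted p = 2.0e-06; adjusted p = 0.86 with an estimated correlation). The nucleoporin genes (Nup) had 17 of 19 higher in shRybp and 0 lower, a median log2 fold change of 0.36 and a camera adjusted p of 2.0e-06 (adjusted p = 0.86 with an estimated correlation). Nup210, which encodes a membrane protein of the nuclear pore, rose most, from 11.8 to 20.1 FPKM (log2 fold change 0.73, edgeR adjusted p = 9.5e-06). Secreted metalloprotease genes of the Adamts family rose too, 8 of 10 with 0 lower and a median of 0.46 (camera adjusted p = 0.0015; adjusted p = 0.86 with an estimated correlation), led by Adamts14 (1.02). Of 13 Sox transcription factor genes 6 fell and 1 rose (median -0.23, camera adjusted p = 0.0056; adjusted p = 0.86 with an estimated correlation), from Sox10 (-1.99) to Sox11 (0.29). The medians of these families kept their sign under each of 6 other scalings.

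The falls of astrocyte markers and rises of S phase genes had the smallest camera p-values of the lists with the preset correlation, though not both with an estimated correlation or fry, and the 4 pairs of an shRybp with a control library gave astrocyte medians of -0.75, -0.62, -0.65 and -0.58. After a trend of the fold changes on GC content and gene length was removed the astrocyte median was -0.70 and the S phase median 0.45, so such a trend is not the whole cause. With each library thinned to the smallest total the medians were -0.69 and 0.48. Thinning keeps the expected share of each gene in its library, so the medians could hardly move. Thinning therefore does not decide whether depth is a cause. The shRybp 2 library had more counts than control 2 (16400480 and 15938646). That pair still had an astrocyte median log2 FPKM ratio of -0.58 and an S phase median of 0.50. These values argue against depth as the whole cause for these 2 lists. A lower share of glia-like cells in shRybp stays possible, since 1 of 19 astrocyte markers rose and 16 fell, and bulk RNA of progenitors that themselves express such genes does not tell a change in cell shares from a change in expression per cell. A direct effect of Rybp depletion on these genes and an effect of the virus or culture cannot be told apart with 1 hairpin label and 2 libraries per group.

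Genes of glycolysis and hypoxia differed between replicate numbers in both groups. The median log2 FPKM ratio of replicate 2 to replicate 1 over 23 genes was 0.48 in control and 0.30 in shRybp, with 22 genes higher in replicate 2 in each group, against medians of 0.01 and 0.01 over all tested genes. A condition shared by the libraries of 1 number stays open, since the value that raised it (lower of the medians, 0.30) cannot also test it, the labels name no such condition and no biological explanation was tested. The median of the list between groups was -0.22 for shRybp 1 over control 1, and -0.43 for shRybp 2 over control 2, below 0 in both same-numbered pairs, and it was -0.73 for shRybp 1 over control 2 and 0.13 for shRybp 2 over control 1.

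Transcripts of mature myelin and of microglia were present in control 2 and shRybp 1 and nearly missing from the other libraries. Mobp had 0, 162, 167 and 1 counts in control 1, control 2, shRybp 1 and shRybp 2, Mag had 5, 116, 121 and 0, and the microglial gene Ctss had 0, 27, 39 and 0. Of 14 myelin and microglia genes from the lists, 10 were higher in both of these libraries than in both others, against 7.46% of all genes. Whole brain tissue is argued against, since the neuron list had a median log2 ratio of 0.0719 between the same pairs, and so is a swap of labels, since control 2 correlated better with control 1 than with shRybp 1 by 0.013. The ratio of shRybp 1 to control 2 over these genes had a median of 0.19 and an interquartile range of 0.28 (log2), so 1 source of RNA or of cells may have reached both libraries, and carry-over between libraries and a few mature glia in the cultures cannot be told apart from these counts.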
